A study of Homo sapiens with 6 samples.

How the data were processed

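Total RNA of 3 cultures in flasks (2D) and 3 in gel (3D) of HBEC3 cells was extracted with RNeasy columns, labelled with biotin using the Illumina TotalPrep kit and hybridized to 6 Illumina bead arrays, per the labels' protocols. HBEC3 is a human bronchial epithelial line known to have been immortalized with CDK4 and TERT. Groups and replicate numbers were taken from the sample titles, and the series' design text states that the cultures were independent. No slide, scan date or other batch was given in the sources used here.

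A deposited table gives the average bead intensity of 48803 probes on each array, not normalized, per the file headers. The intensities were linear and at least 82.5 on every array, so no background had been subtracted. Beside each intensity the deposited table gives a detection p-value, per the file headers, which moves in steps that correspond to 759 negative control bead types. A second deposited table holds the authors' processed intensities. Their method is not given in the sources used here; each array's column rises with its intensity in the first table without exception, and the scale is linear. Sorted, the 6 columns differ by at most 0.0759% at any rank, where median-scaled intensities differ by up to 37.1%, so the values are quantile normalized. Their lowest value, 12.1, lies below the lowest intensity, 82.5, so a background had been taken off in a way not given here. The software and its version are not given in the sources used here.

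The intensities were background-corrected and normalized with neqc in limma 3.58.1 (R 4.3.3), which fits a normal and exponential model to the signal, infers the negative controls from the detection p-values, adds an offset of 16 and equalizes the quantiles of the arrays, and were then put on the log2 scale. The offset shrinks fold changes of dim probes, and background correction widens them. A probe was kept with a detection p under 0.05 on at least 3 of the 6 arrays, which 16725 probes passed. A platform annotation named 1 gene for 27578 probes, several for 13 and none for 21212, which are unnamed here. Symbols were updated through gene IDs with an annotation of GRCh38.p14, where the IDs of 27541 probes matched; no coordinates are given because the build behind the array is not given in the sources used here. Of the probes kept, 14032 had 1 gene and 2693 had none or several. Each of the 10695 genes was represented by its probe with the highest mean signal; 7977 genes had 1 probe and 2718 had more. Of these 2718, 2073 had a probe past the threshold and 91 had probes past it in both directions.

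Differences (3D minus 2D) were tested with limma's lmFit and eBayes with a mean-variance trend, and p-values were adjusted by Benjamini-Hochberg over all genes tested. Errors of fold changes are standard errors of the fit, and errors of signals are SDs over 3 arrays. A gene none of whose probes was above background on any array of a condition has only a bound there: its fold is given as at least the ratio of the bright condition's mean to the dim condition's mean, where each dim array contributes the higher of its lowest detected signal and the probe's own. The same bound is given for a named gene above background on 1 array of its dim condition, or whose brightest probe was on none. The 25 gene lists were fixed before the data were examined. They hold 658 symbols, of which 480 were tested, 133 were below the filter and 45 had no probe named here, and 3 older symbols were matched through synonyms. Lists were tested with limma's camera with a preset correlation of 0.01 between genes, adjusted over the lists, and again with an estimated correlation and with fry. Camera compares a list with the other genes, while fry asks whether the genes of a list move one way on balance.

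Named genes follow a rule fixed at the same time: the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold whose groups do not overlap, leaving out provisional symbols; up to 4 members of each list with the largest change past the threshold, filled up to 2; and CDK4 and TERT. Other members named where a count is 5 or fewer, or as examples of undetected genes, were chosen after their values were seen.

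The steps were tested on simulated data with the means and spreads of the 10695 genes, 200 of them changed, in 20 runs for the comparison of 3D with 2D. Of genes changed 1.41-fold 48.1% were recovered, of those changed 2-fold 97.5% and of those changed 4-fold 100%, with 7.29% false genes among the calls. A shifted list was found in 20 of the 20 runs with the preset correlation. The simulated genes were independent of each other, few of them were changed and no array stood apart. In the real data 6619 genes passed, and the estimated correlation was 0.42 for the mitosis list. The runs therefore do not show how the list test or the share of false genes fares under those conditions. Alternatives for background correction, normalization, filter, probe choice, variance model, array weights, replicate block, set test and left-out arrays were fixed in advance as well, and the member counts of the lists without 3D replicate 3 were added later. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. With 32.7% to 33.9% of probes above background, signal near background limits what can be said about the other probes.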

Results

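Gene expression was measured in HBEC3 cells, a line of human bronchial epithelial cells, which line the large airways and can form basal, secretory, ciliated and, under some conditions, squamous cells. The cells grew either in culture flasks (2D) or in a gel (3D), and 3 independent cultures of each kind were profiled, 1 bead array per culture, 6 arrays in all. An array carried 48803 probes, of which 15983 to 16568 (32.7% to 33.9%) were above background on an array at a detection p under 0.05. Over the 10695 genes tested, the arrays of the 2D cultures correlated with each other at r = 0.996, 3D replicates 1 and 2 at r = 0.995, and 3D replicate 3 with these at r = 0.987 and r = 0.986, while arrays of different conditions correlated at r = 0.884 to 0.889. These correlations run across genes, which are not independent replicates. The number of arrays, 3 per condition, limits the precision of all values below.

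The comparison asked how expression in 3D culture differs from that in 2D culture. In 3D culture, genes of squamous differentiation such as SPRR1A and S100A8, and many hypoxia and p53 target genes were higher. So were 5 of 6 tested fibroblast markers, DCN among them, while 14 other fibroblast markers were below the detection filter. Most genes of the cell cycle, sterol synthesis and EGFR and MAPK feedback, such as BIRC5, INSIG1 and SPRY4, and some genes of the actin cytoskeleton, such as TPM4, were lower. These groups passed a test with a preset correlation between genes, and none of them passed with an estimated correlation, a test that rests on the few residual degrees of freedom of 6 arrays. The hypoxia and p53 groups also failed to pass under another setting each, given below. Of 10695 genes, 6619 (61.9%) passed an adjusted p of 0.05 in limma, with 3259 higher and 3360 lower in 3D. A change of at least 2-fold was reached by 1229 genes that were higher and 1080 that were lower, 2309 together. At 8-fold, 179 genes were higher and 73 lower. The 3 values of one condition all lay above the 3 of the other for 7126 genes (66.6%), where chance gives 10%. Among the genes called higher in 3D, 305 were not above background on any 2D array, and among those called lower, 158 were not above background on any 3D array. The number changed at least 2-fold was 1295 when only genes above background on all 6 arrays at a detection p under 0.01 were tested, 1471 without background correction and 1306 when the test itself was set against a 2-fold change. Without 3D replicate 3, the array that correlated least with its group, 7339 genes changed, 2377 of them at least 2-fold.

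Of the 12 genes with the largest fitted rise in 3D, 7 were members of the squamous differentiation list; where a gene was not above background in 2D its place in that order is not certain. GPR15LG, which encodes a secreted ligand of the receptor GPR15, had a normalized log2 signal of 13.89 ± 0.15 in 3D (SD, n = 3) and was not above background in 2D, so that it was at least 296-fold higher (limma adjusted p = 7.20e-13). The cornified envelope precursors SPRR1A and SPRR3 were at least 267-fold and at least 144-fold higher, and neither was above background in 2D. SPRR1B rose by 7.35 ± 0.10 on the log2 scale (SE). KRTDAP, a secreted protein of differentiating keratinocytes, was above background on 1 of the 3 2D arrays and rose by 8.57 ± 0.15, or at least 346-fold. The calcium-binding protein S100A8, a subunit of calprotectin, went from 7.01 ± 0.13 in 2D to 15.25 ± 0.11 in 3D (SD, n = 3), a log2 fold change of 8.24 ± 0.10 (SE), and S100A7 was at least 104-fold higher. Suprabasin (SBSN) was at least 77.8-fold higher, and the protease inhibitor SERPINB13 at least 90.1-fold. SERPINB3, an inhibitor known as a squamous cell carcinoma antigen, rose by 7.07 ± 0.15. The xenobiotic-metabolizing enzyme CYP1B1 was at least 95.8-fold higher. FGFR3, a receptor for fibroblast growth factors, rose by 8.01 ± 0.10 and was above background on 2 of the 3 2D arrays. A second FGFR3 probe had a log2 fold change of -0.22 (adjusted p = 0.333), so the rise was seen with 1 of the 2 probes that passed the filter. That second probe was near background in both conditions, at 5.85 in 2D and 5.62 in 3D.

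The 12 genes with the largest fall in 3D had differing known functions. IL13RA2, a decoy receptor for interleukin 13, was above background on 1 of the 3 3D arrays and was at least 44.2-fold lower in 3D (adjusted p = 5.82e-11). FOXA2, a transcription factor of endodermal epithelia, went from 11.54 ± 0.03 in 2D to 6.23 ± 0.19 in 3D (SD, n = 3), a log2 fold change of -5.30 ± 0.13 (SE, limma adjusted p = 5.30e-11). The fall was seen with 1 FOXA2 probe, and the others were at or near background in both conditions. The interstitial collagenase MMP1 fell by 4.92 ± 0.16. TNFRSF6B, a soluble decoy receptor of the TNF family, was above background on 1 3D array and at least 21.7-fold lower. The transcription factors ETV5 and FOSL1 and the pleckstrin homology-like protein PHLDA1 had log2 fold changes of -4.46 ± 0.17, -4.32 ± 0.22 and -3.96 ± 0.14. Among cell cycle genes, the kinetochore gene SPC25 fell by 4.35 ± 0.15, the phosphatase gene CDKN3 by 3.91 ± 0.13, and RRM2, a subunit of ribonucleotide reductase, by 3.81 ± 0.25. The phospholipid-binding protein ANXA3 and the membrane protein CMTM7 fell by 4.08 ± 0.12 and 4.07 ± 0.10. All 24 genes had adjusted p-values of 1.32e-07 or smaller.

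**Figure D1:**
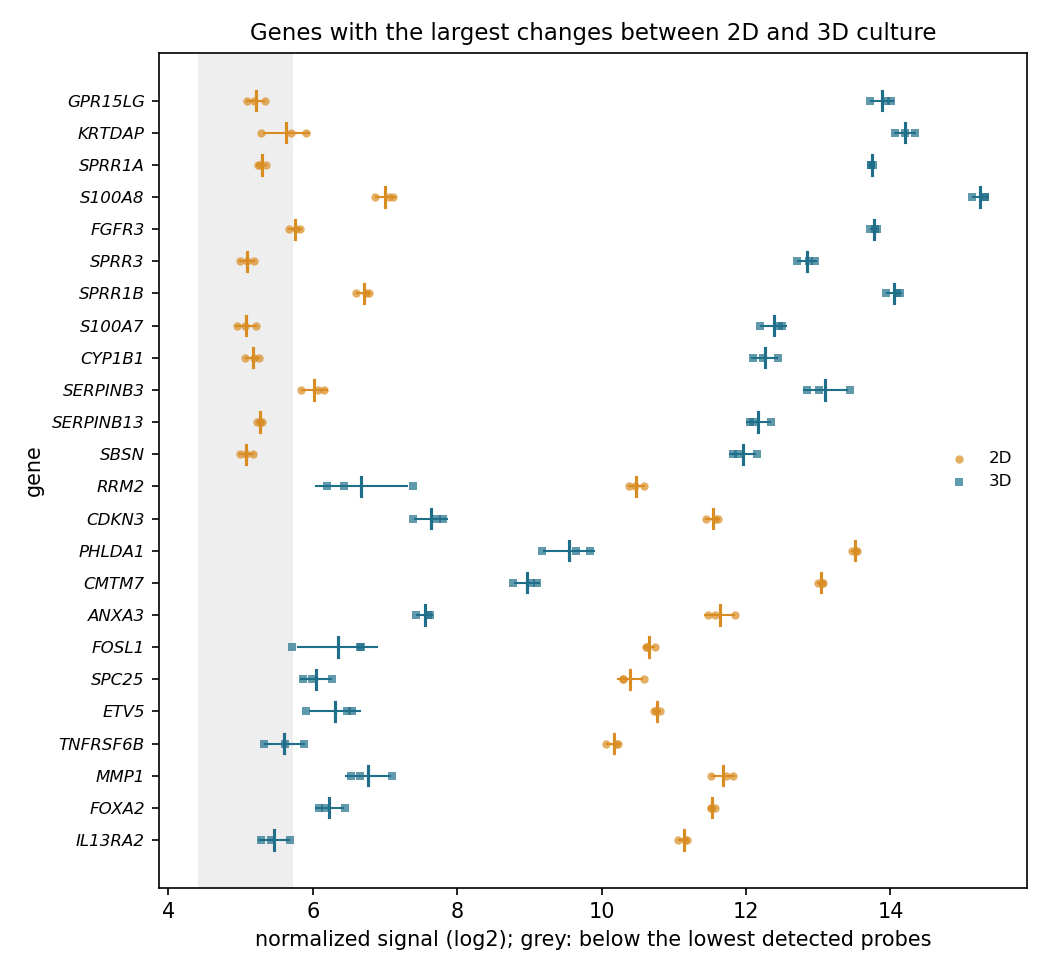
Normalized log2 signal (x axis) of the 12 genes with the largest rise and the 12 with the largest fall in 3D (y axis). Each point is 1 array (circles 2D, squares 3D, 3 each), vertical ticks are means, horizontal bars are 1 SD, and the grey band lies below the lowest detected signal. S100A8 goes from 7.01 in 2D to 15.25 in 3D, and FOXA2 from 11.54 to 6.23.

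Of 25 gene lists fixed in advance, 9 differed from the other genes by camera with a preset correlation of 0.01 between genes, 4 of them upward and 5 downward. With a correlation estimated from the 6 arrays, 0 of the 25 lists passed an adjusted p of 0.05 and 6 had an unadjusted p under 0.05, and that adjusted p is given beside each of the 9. Counts of members are over all genes tested, and they were equal when adjusted over the list alone unless stated. 3D replicate 3 correlated less with its group, and the 9 lists had the same direction without it.

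Squamous differentiation genes rose together. Of 29 tested genes of the cornified envelope and the squamous program, 28 rose and 1 fell, with a mean log2 fold change of 4.54 (camera adjusted p = 3.59e-19; adjusted p = 0.0906 with an estimated correlation). KRTDAP, SPRR1A, S100A8 and SPRR3 had the largest fitted changes, with SPRR1A and SPRR3 not above background in 2D. The member that fell was LCE3D, a late cornified envelope gene, at -0.84 (adjusted p = 0.00765). In 12 of the 29, 1 condition was not above background, so the median of 4.04 is also given with those genes at their bounds, 3.82. Those 12 passed the filter through the other condition alone, which fixed their direction. With a detection p under 0.01 on all 6 arrays, 8 members were left, with a mean of 3.56 (camera adjusted p = 9.69e-08). Another 9 of the 40 listed genes, IVL and TGM3 among them, were below the detection filter, and 2 had no probe named here.

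Airway lineage markers went both ways. Of 14 basal cell markers, 9 rose, 3 fell and 2 did not pass (mean log2 fold change 0.60, median 0.32, camera adjusted p = 0.106). The keratin KRT15 rose by 3.24 ± 0.09 (SE), DAPL1 was at least 3.43-fold and the water channel AQP3 at least 1.88-fold higher with neither above background in 2D, and S100A2 fell by 1.10 ± 0.08. Of 13 secretory cell markers, 5 rose, 5 fell and 3 did not pass (mean 0.28, median -0.06, camera adjusted p = 0.996). CEACAM6 was at least 8.12-fold and the mucin MUC1 at least 7.82-fold higher. MSMB was higher in 3D on its brightest probe (limma adjusted p = 2.42e-06), which was above background on 3D arrays only, at least 2.37-fold. It had a log2 fold change of 0.34 (adjusted p = 0.124) on another probe and of 1.10 on a further one, above background on 3D arrays only. The simple-epithelium keratin KRT18 fell by 2.00 ± 0.09 and had a log2 fold change of -1.59 on another probe, while its dimmest probe had 1.16 (adjusted p = 0.000127). A further 15 secretory markers, the secretoglobin SCGB1A1 among them, were below the detection filter. Of 10 ciliated cell markers, 3 rose, 4 fell and 3 did not pass (mean -0.00069, median -0.09, camera adjusted p = 0.774), and 14 others, FOXJ1 among them, were below the filter. The calcium-binding protein CAPS rose by 1.35 ± 0.18 and the transcription factor RFX2, above background on 2 of the 3 2D arrays, by 1.03 ± 0.21, and CCNO, which acts in the making of motile cilia, fell by 1.07 ± 0.23, as did the tubulin TUBA1A by 0.99 ± 0.08.

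Most cell cycle genes fell. All 34 tested mitosis genes fell, each at least 2-fold, with a mean log2 fold change of -2.70 (camera adjusted p = 3.59e-19; adjusted p = 0.179 with an estimated correlation). BIRC5, part of the chromosomal passenger complex, had a log2 fold change of -3.76 ± 0.17 (SE), the anaphase activator CDC20 of -3.42 ± 0.20, the checkpoint kinase BUB1 of -3.39 ± 0.11 and CDCA3 of -3.33 ± 0.19. Of 31 DNA replication and S phase genes, 29 fell, 1 rose and 1 did not pass, with a mean of -1.70 (camera adjusted p = 3.37e-12; adjusted p = 0.094 with an estimated correlation). After RRM2 the largest falls were those of the thymidine kinase TK1 at -3.57 ± 0.13, and of CDC45 and GINS2, parts of the replicative helicase, at -2.79 ± 0.15 and -2.73 ± 0.20. The gene counted as higher was ORC6, by 0.38 on its brightest probe, while its other probe fell by 3.00, and E2F1 did not pass, at 0.18. For the genes used to immortalize this line, CDK4 had a signal of 11.97 ± 0.08 in 2D and 11.43 ± 0.21 in 3D (SD, n = 3), a log2 fold change of -0.54 ± 0.11 (SE, limma adjusted p = 0.00113). TERT had 8.60 ± 0.19 and 8.11 ± 0.22 (SD, n = 3), a log2 fold change of -0.49 ± 0.15 (SE, limma adjusted p = 0.0158). Another TERT probe was not above background on any array, at 5.22 in 2D and 5.21 in 3D. The TERT call ended without 2D replicate 2 (-0.39) and without 3D replicate 2 (-0.38).

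Most growth factor feedback genes fell, and actin cytoskeleton genes were lower in part. Of 21 genes induced by EGFR and MAPK signalling, 18 fell and 3 rose, with a mean of -2.21 (camera adjusted p = 9.68e-08; adjusted p = 0.0861 with an estimated correlation). ETV5, FOSL1, PHLDA1 and the feedback inhibitor SPRY4, at -3.66 ± 0.13 (SE), led the falls, and the 3 that rose were DUSP1 at 0.72, MYC at 0.70 and FOS at 0.33. Of 24 SRF-regulated actin cytoskeleton genes, 12 fell, 1 rose and 11 did not pass, with a mean of -0.45 (camera adjusted p = 0.0168; adjusted p = 0.169 with an estimated correlation). Tropomyosin TPM4 fell by 2.44 ± 0.20, alpha-actinin ACTN1 by 1.99 ± 0.14, LIMA1 by 1.46 ± 0.11 and TGFB1I1 by 1.04 ± 0.14, and the smooth muscle actin gene ACTA2 rose by 1.02. Without 3D replicate 3, 17 members of this list fell and 2 rose. Of 18 YAP and TAZ targets, 9 fell, 6 rose and 3 did not pass (mean -0.59, camera adjusted p = 0.206), and the largest changes were falls in CCN2 at -2.99 ± 0.14, NT5E at -2.47 ± 0.09, tissue factor F3 at -2.18 ± 0.10 and DOCK5 at -1.71 ± 0.15.

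Most sterol synthesis genes fell, and more hypoxia-induced genes rose than fell. Of 20 sterol synthesis and SREBP2 target genes, 15 fell, 2 rose and 3 did not pass (3 rose when adjusted over the list alone), with a mean of -1.02 (camera adjusted p = 0.000102; adjusted p = 0.094 with an estimated correlation). The sterol sensor INSIG1 had a log2 fold change of -2.93 ± 0.12 (SE), ACAT2 of -2.77 ± 0.09, the synthase HMGCS1 of -2.52 ± 0.08 and the isomerase IDI1 of -2.51 ± 0.10. The members that rose were TM7SF2 at 1.25 and HSD17B7 at 0.66. Of 25 hypoxia-induced and glycolytic genes, 15 rose, 4 fell and 6 did not pass, with a mean of 0.64 (camera adjusted p = 0.0204; adjusted p = 0.169 with an estimated correlation). The prolyl hydroxylase EGLN3 rose by 3.59 ± 0.16, adrenomedullin (ADM) by 1.93 ± 0.09, the glucose transporter SLC2A1 by 1.72 ± 0.07 and MXI1 by 1.68 ± 0.17. The 4 that fell were ANGPTL4 at -1.02, the glycolytic enzymes PGAM1 and TPI1 at -0.62 and -0.49, and LDHA, which makes lactate, at -0.18. The list did not pass when only genes above background on all 6 arrays were tested (mean 0.46, adjusted p = 0.0765). Of 29 nuclear genes of oxidative phosphorylation, 11 fell, 3 rose and 15 did not pass (10 and 2 when adjusted over the list alone; mean -0.13, camera adjusted p = 0.280). SDHA fell by 1.13 ± 0.08, NDUFA9 by 0.73 ± 0.10 and COX8A by 0.67 ± 0.08, and NDUFB5 rose by 0.52 ± 0.08.

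**Figure D2:**
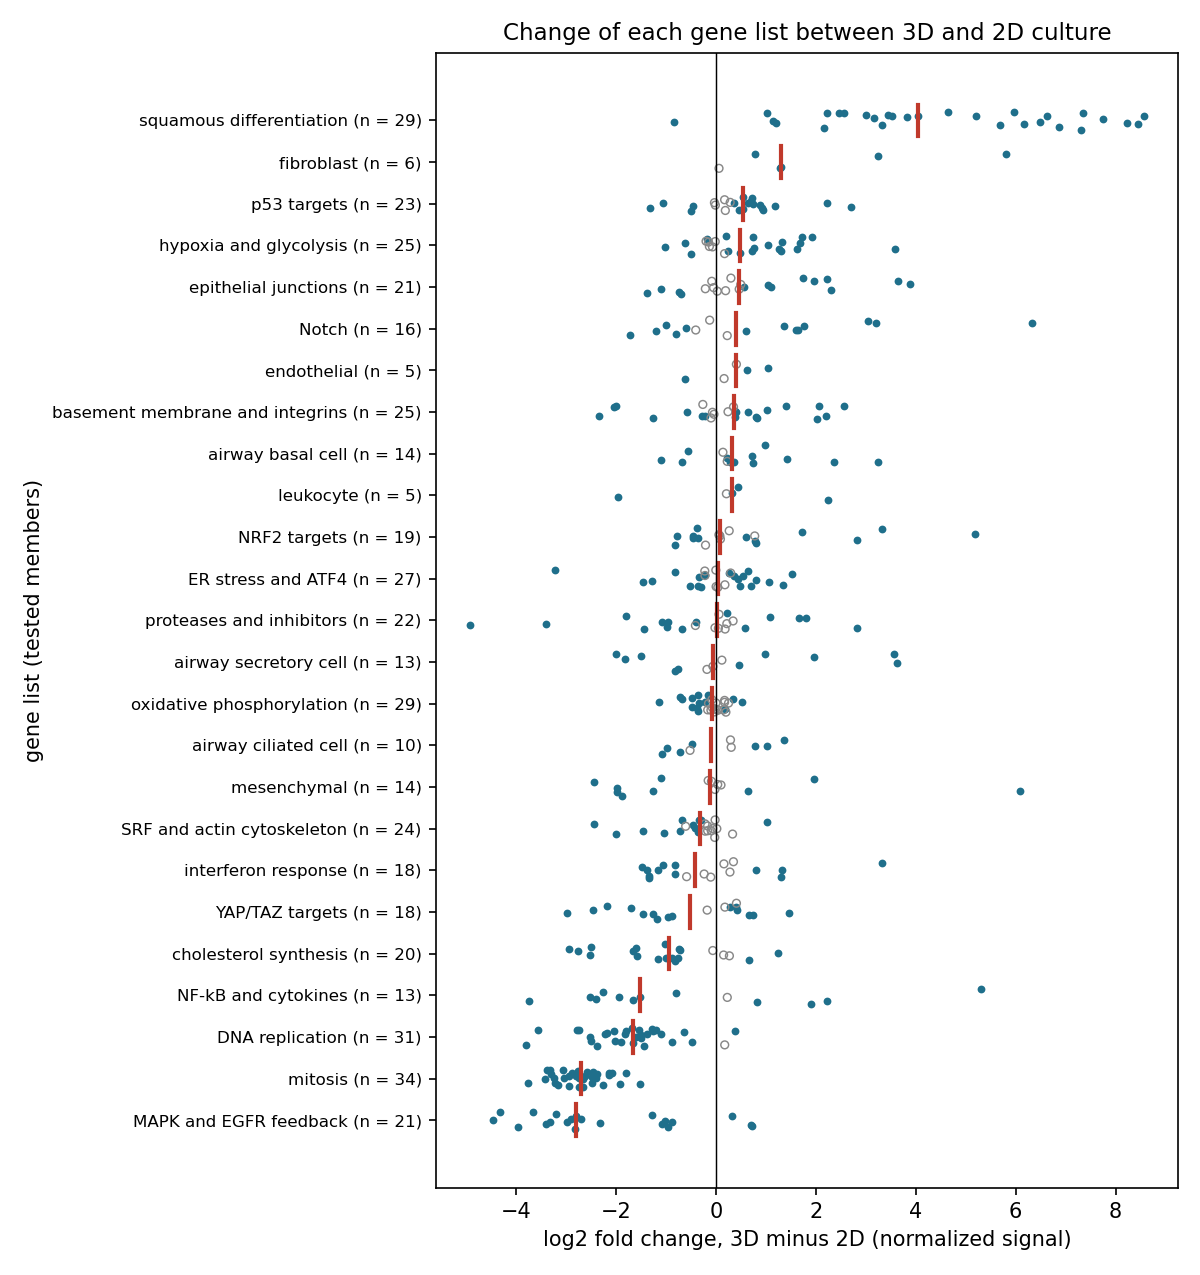
Log2 fold change, 3D minus 2D (x axis), of the tested members of the 25 gene lists (y axis, with the number of members). Filled points passed an adjusted p of 0.05, open points did not, and red ticks are list medians. The medians run from -2.80 for the MAPK and EGFR list to 4.04 for squamous differentiation.

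Cell junction and matrix genes changed in both directions. Of 21 epithelial junction genes, 9 rose, 4 fell and 8 did not pass (10 rose when adjusted over the list alone; mean 0.75, median 0.47, camera adjusted p = 0.0822). The claudin CLDN1 rose by 3.89 ± 0.11 (SE), cingulin (CGN) by 3.64 ± 0.15 and desmoplakin (DSP) by 2.22 ± 0.09, and CLDN8 was at least 3.17-fold higher. The members that fell were PKP2, EPCAM, AP1M2 and TJP1. Of 25 basement membrane and integrin genes, 12 rose, 7 fell and 6 did not pass (13 rose when adjusted over the list alone; mean 0.25, camera adjusted p = 0.301). Dystonin (DST), of hemidesmosomes, rose by 2.57 ± 0.09 and the laminin chains LAMB2 and LAMB1 by 2.21 ± 0.18 and 2.07 ± 0.11, and thrombospondin THBS1 fell by 2.34 ± 0.14. Of 22 matrix proteases and their inhibitors, 6 rose, 9 fell and 7 did not pass, with a mean of -0.32 and a median of 0.02 (camera adjusted p = 0.653). After MMP1, the plasminogen activator PLAT fell by 3.41 ± 0.15 and the urokinase receptor PLAUR by 1.80 ± 0.16, while the inhibitor TIMP3 rose by 2.82 ± 0.11. Of 14 genes of epithelial to mesenchymal transition, 3 rose, 6 fell and 5 did not pass (mean -0.15, camera adjusted p = 0.239). The collagen crosslinking enzyme LOX rose by 6.09 ± 0.16, and TNFRSF12A fell by 2.44 ± 0.08, PMEPA1 by 1.99 ± 0.08 and vimentin (VIM) by 1.98 ± 0.09.

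Notch, cytokine and p53 genes held both rises and falls. Of 16 Notch pathway genes, 8 rose, 5 fell and 3 did not pass (mean 0.87, median 0.41, camera adjusted p = 0.239). The receptor NOTCH3 was at least 57.0-fold higher and not above background in 2D, NOTCH1 rose by 3.21 ± 0.16 (SE), HES2 by 3.04 ± 0.09 and the ligand JAG2 by 1.75 ± 0.11. Those that fell were DLL3, MFNG, HEY2, NOTCH2 and JAG1. Of 13 cytokine and NF-kB target genes, 8 fell, 4 rose and 1 did not pass, with a mean of -0.49 and a median of -1.53 (camera adjusted p = 0.206). The interleukins IL1B and IL1A fell by 3.74 ± 0.08 and 2.52 ± 0.10. CXCL8, above background on 1 3D array, was at least 5.03-fold lower. IL1RN, the natural antagonist of IL1B and IL1A, rose by 5.32 ± 0.13 on its brightest probe. It rose by 0.77 on a dimmer probe, and a further IL1RN probe was not above background on any array. Of 23 p53 targets, 14 rose, 4 fell and 5 did not pass, with a mean of 0.47 (camera adjusted p = 0.0204; adjusted p = 0.323 with an estimated correlation). TP53INP1 rose by 2.69 ± 0.14, SESN1 by 2.23 ± 0.12 and SESN2 by 1.19 ± 0.17. The 4 that fell were AEN, by 1.33 ± 0.10, MDM2, SFN and FAS. The p53 list did not pass when all probes of a gene were averaged (mean 0.40, adjusted p = 0.0724).

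Of 19 NRF2 targets, 7 rose, 6 fell and 6 did not pass (8 rose when adjusted over the list alone; mean 0.69, median 0.09, camera adjusted p = 0.206). The aldo-keto reductases AKR1B10, AKR1C3 and AKR1C2 rose by 5.19 ± 0.08, 3.32 ± 0.10 and 2.83 ± 0.09 (SE), and pirin (PIR) rose by 1.73 ± 0.13. The aldo-keto reductases are closely related in sequence, so a probe may not tell 1 from another. Of 18 interferon-stimulated genes, 4 rose, 8 fell and 6 did not pass (mean -0.15, median -0.41, camera adjusted p = 0.525). IFI44L was at least 7.83-fold higher, and OAS3 fell by 1.49 ± 0.14, ISG15 by 1.35 ± 0.16 and IFIT1, above background on 2 3D arrays, by 1.37 ± 0.24. Of 27 unfolded protein and amino acid response genes, 11 rose, 9 fell and 7 did not pass (12 rose when adjusted over the list alone). The mean was -0.01, the median 0.04 and the camera direction upward, with an adjusted p of 0.766. TRIB3 fell by 3.22 ± 0.11 and asparagine synthetase (ASNS) by 1.46 ± 0.13, and VLDLR and SLC3A2 rose by 1.52 ± 0.13 and 1.35 ± 0.12.

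Markers of cell types other than epithelium were mostly below background. Of 20 fibroblast genes 6 were tested, and 5 of these rose while MMP2 did not pass, at 0.06, with a mean of 2.08 and a median of 1.30, or 1.06 with 3 members at their bounds (camera adjusted p = 0.011; adjusted p = 0.286 with an estimated correlation). The proteoglycan decorin (DCN) was at least 42.8-fold higher, the collagens COL1A1 and COL5A2 at least 6.77-fold and at least 1.79-fold, none of them above background in 2D, and PDGFRA rose by 1.28 ± 0.17 (SE). The fifth was FAP, at 0.79. The other 14 fibroblast genes were below the filter, COL1A2, COL3A1 and LUM among them, and do not enter the mean or the test. DCN, COL1A1 and COL5A2 passed the filter through their 3D arrays alone, which fixed their direction. The mean and the p-values of this list rest in part on that selection. Of 5 tested endothelial genes, 2 rose, 1 fell and 2 did not pass (mean 0.32, camera adjusted p = 0.525). VWF was at least 1.29-fold and KDR at least 1.24-fold higher, and PECAM1 fell by 0.62 ± 0.16. Of 5 tested leukocyte genes, 3 rose, 1 fell and 1 did not pass (mean 0.25, camera adjusted p = 0.412). CD14, a receptor for lipopolysaccharide, rose by 2.24 ± 0.09 and LCP1 was at least 2.50-fold lower, not above background in 3D. CD68 rose by 0.32 ± 0.08, while another of its probes had -0.09 (adjusted p = 0.720). CD79A was at least 1.04-fold higher (limma adjusted p = 0.0318), and its call ended with any 1 of the 6 arrays left out (adjusted p up to 0.104).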

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

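The count of unnamed probes was chosen only after the results for named genes were seen. Probes with no gene named here enter no comparison above, and many of them differed between the conditions. Of 2693 such probes above background, 730 were higher in 3D and 685 were lower (limma, adjusted over these and the other probes kept), and 241 were at least 2-fold higher and 242 at least 2-fold lower. They drew attention as a signal in data outside the named genes. No explanation was tested.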

How the results depend on the processing

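The settings compared here were fixed in advance, and only the member counts of lists without 3D replicate 3 were chosen after the results were seen. The number of changed genes lay between 4702 and 7341 over the alternatives, and between 5779 and 7339 with 1 array left out, the highest without 3D replicate 3. The number changed at least 2-fold was 1471 without background correction, 1295 with a detection p under 0.01 on all 6 arrays, where 7247 genes were tested, and 1306 with treat; the cause of the first was not tested. Any pairing by replicate number was weak: deviations of same-numbered arrays correlated at 0.0111, 0.0465 and 0.0435, and those of other pairs at -0.0678 to 0.0192. Every array but 2D replicate 1, at 0.0192 with 3D replicate 2, correlated best with its own number. A replicate block gave 6621 changed genes, 2309 of them at least 2-fold, so pairing hardly altered the counts. The slide as a block was not run, since the files name no slide.

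Of 471 list values, 434 kept direction and call, 11 lost the call, 14 gained it and 12 changed sign. Part of the 434 was fixed in advance. The other variance models, the replicate block, the estimated correlation and fry leave the mean of a list as it was, so its sign could not change. With the robust variance model the list test was that of the main setting, so no call could change either. With an estimated correlation the calls ended for mitosis (-2.70), DNA replication (-1.70), cholesterol synthesis (-1.02), hypoxia and glycolysis (0.64), squamous differentiation (4.54), fibroblast (2.08), SRF and actin (-0.45), MAPK and EGFR (-2.21) and p53 targets (0.47), at unchanged means. This test has the few residual degrees of freedom of 6 arrays in place of those of all genes, besides another variance. The estimate was below the preset 0.01 for cholesterol synthesis (0.0095), hypoxia and glycolysis (-0.015), SRF and actin (-0.0040) and MAPK and EGFR (-0.0020). A larger correlation was thus not what ended those calls. For the other lists named here it was above 0.01, up to 0.42 for mitosis. Hypoxia and glycolysis was not called with the stricter filter (0.46), nor p53 targets with probes averaged (0.40). With fry, which does not compare a list with other genes, calls were gained by oxidative phosphorylation (-0.13), basement membrane (0.25), proteases (-0.32), basal (0.60), secretory (0.28), junctions (0.75), mesenchymal (-0.15), leukocyte (0.25), YAP/TAZ (-0.59), NF-kB (-0.49), NRF2 (0.69) and Notch (0.87). Without a filter, calls were gained by basal (0.60) and junctions (0.75), with the same 14 and 21 members as before. Only the set of genes these lists were compared with grew, to 18665. The gains therefore say nothing on members below the filter. Signs changed in lists that were not called: proteases (0.27) and secretory (-0.83) with the stricter filter, ciliated with median scaling (0.13), the authors' values (0.032) and array weights (0.0051), and the unfolded protein and amino acid list with median scaling (0.0244) and averaged probes (0.0092). With 1 array left out these last lists ranged from -0.0595 to 0.0348 and from -0.0287 to 0.000304. The stricter filter left under 5 members of the ciliated, fibroblast, endothelial and leukocyte lists, which gave no value. The causes of sign changes were not tested.

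Of 1964 values of the 116 named genes, 1950 kept direction and call, 11 lost the call (TERT, CD79A, MSMB and CD68) and 3 changed sign, all on another probe of the gene: FGFR3 (-0.22), KRT18 (1.16) and CD68 (-0.0856). The median change of all genes was -0.01 in the main setting and 0.05 with median scaling. Signal over background limits all of this: genes below background in a condition have bounds only.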

Other observations

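The gene families, the correlation of neighbouring genes, both tests of the fibroblast markers and the test of a smaller or larger move of 3D replicate 3 were chosen only after the results were seen, and the other tests were written before their own results. Of 40 families, 16 differed from the other genes by camera with a preset correlation, 8 upward and 8 downward, and 0 with an estimated correlation, where 8 had an unadjusted p under 0.05 and the adjusted p for those named here was 0.219 or more. The families named here had the same sign of mean change in all 5 normalizations. Centromere proteins of the CENP group fell in 17 of 22 members and rose in 1 (mean log2 fold change -1.70, camera adjusted p = 2.03e-06). Kinesins fell in 16 of 25 and rose in 5 (-1.03, adjusted p = 0.0056), and tubulins fell in 9 of 15 and rose in 2 (-0.76, adjusted p = 0.013). Beyond cell division, proteasome subunits fell in 27 of 37 members and rose in 5 (-0.51, camera adjusted p = 0.000303), led by PSMD2 at -2.01. Mitochondrial ribosomal proteins fell in 50 of 78 and rose in 8 (-0.34, adjusted p = 0.000295), and their largest change was a rise, MRPS25 at 1.49. Nucleoporins fell in 14 of 22 with 0 rising (-0.53, adjusted p = 0.00607).

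Kruppel-like factors rose in 9 of 12 members and fell in 1 (mean 0.81, camera adjusted p = 0.013), with KLF5 at 1.86, KLF9 at 1.84 and KLF4, a factor of epidermal barrier formation, at 1.54. Cathepsins rose in 9 of 12 (0.81, camera adjusted p = 0.0152), connexins in 5 of 7 (1.56, adjusted p = 0.0194), with GJB2 at 4.74, ephrins and Eph receptors in 7 of 12 (0.89, adjusted p = 0.0194) and protocadherins in 10 of 20 (0.78, adjusted p = 0.0194). In each of these families 1 member fell. Of 293 ZNF zinc finger genes, 113 rose and 34 fell (0.28, adjusted p = 0.013). Keratins split, with 13 of 20 higher and 5 lower (1.65, adjusted p = 0.00627). KRT13, KRT4 and KRT1, of stratified epithelia, were at least 64.9-fold, at least 46.9-fold and at least 39.5-fold higher, and the hair keratin KRT34 was at least 7.07-fold lower.

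Neighbouring genes on a chromosome changed together. Over 10469 pairs of adjacent tested genes the log2 fold changes correlated at 0.11, and the highest of 10000 shuffles gave 0.0411 (permutation p = 1e-04, the smallest these shuffles can give). Families of related genes lying side by side are a candidate explanation: a window of 6 genes around SPRR1A had a median of 5.69 and one around S100A8 of 5.04, both above the highest window of 200 shuffles, 4.27. Without pairs whose symbols share their first 3 letters, 10007 pairs gave 0.0605, above the highest of their shuffles, 0.0405. That does not exclude related neighbours, since relatives with unlike names stay among those pairs, such as DSC2 at 3.82 beside DSG1 at 2.23 and IL1B at -3.74 beside IL37 at -2.48. Related neighbours, cross-hybridization between them and regulation over larger regions all stay open, and cross-hybridization and regulation over regions were not tested.

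Of 20 listed fibroblast markers, 5 were higher in 3D, DCN by at least 42.8-fold and COL1A1 by at least 6.77-fold (adjusted p = 0.286 for the list with an estimated correlation). Fibroblasts in the 3D cultures are a candidate source. Of the 20 genes, 14 had no probe above background on 2 or more 3D arrays, COL1A2 and COL3A1 among them, while COL1A1 was above background on all 3. On their brightest probes these 14 had mean 3D signals of 4.94 (THY1) to 5.67 (COL6A2) on the log2 scale, against 11.1 for DCN and 8.44 for COL1A1. Where the probes can detect their genes, that argues against fibroblasts as the source of DCN. It does not settle the question, since the 14 had already failed the detection filter when the test was written. Of the 20, 3 were above background on 2 or more 2D arrays, and 1 stands in another list too. The list's lowest mean over the 4 other normalizations was 1.30, so its direction did not depend on which of them was used. This test could hardly have come out otherwise. DCN and COL1A1 were above background on 3D arrays only, by detection p-values given with the intensities before normalization. Of 4 DCN probes 2 rose, and whether the silent probes can detect their genes was not tested. Fibroblasts in the cultures are thus not excluded, and a change within the epithelial cells in gel stays open.

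3D replicate 3 stood apart from the other 3D arrays, with an array weight of 0.224 against 1.00 to 1.54 for the others. Noise of dim probes would spare bright genes. Among the 2674 brightest genes its deviation was 2.49 times that of the other 3D arrays, scaled so that equal noise gives equal deviations. A smaller or larger move from 2D to 3D would follow the change itself, which accounted for 1.85% of the variance of its deviation. In 5 of 5 normalizations both its correlations lay below that of the other 3D arrays, which argues against the normalization. RNA quality, a difference between the cultures and the array itself stay open and were not tested.

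Splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. The real split gave 6619 changed genes and the other 9 gave at most 0 (limma; 23 to 132 genes at an unadjusted p under 0.05), and for changes of at least 2-fold it gave 2309 against at most 0. In both cases 1 of the 10 splits, the real one, gave as many. The other 9 splits mix 2D and 3D arrays in both groups. The difference between the cultures then widens the spread within their groups and lowers their counts, so the comparison does not measure chance.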
